A study of Mus musculus with 13 samples.

How the data were processed

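Total RNA from pieces of liver and kidney of 8-week-old CD-1 (ICR) mice was sequenced as 13 libraries. Per the labels' protocols, oocytes were either used fresh or vitrified on a Cryotop carrier and thawed, then fertilised in vitro, and cleaved embryos were transferred to pseudopregnant females. Tissue was rinsed with saline and ground in liquid nitrogen, and the library protocol in the labels lists both removal of ribosomal RNA and isolation of mRNA. The groups were taken from the treatment and tissue labels, with 3 fresh and 3 vitrified livers and 3 fresh and 4 vitrified kidneys. The labels call these biological replicates. They give no sex, litter, parent, day or batch, and do not say that equal replicate numbers in both organs mark the same mouse, so p-values measure the spread between these samples.

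The deposited table held, for 22298 genes and each library, an estimated count and an FPKM value made by the authors. Per the submitters' processing notes, Bowtie2 2.2.8, HISAT2 2.4, StringTie 1.3.1 and DESeq2 were used with the genome build GRCm39. The notes as held here give no role or order for the tools, and the counting settings and strand use are not given in the sources used here. Of the estimated counts, between 7.63% and 9.14% per library were not whole, and they were rounded to whole numbers before any count model. Estimated counts can divide reads between near-identical genes, so such genes are reported as uncertain. Totals lay between 16073251 and 19964914 per library. Of the gene identifiers, 22255 were found in GENCODE mouse release 21, which was used only for names, gene classes and transcript sequence, because its build differs from that of the table, and no coordinates are given. Protein-coding genes made up 97.7% of the table. No pair of libraries of the same group or organ agreed within sampling noise (chi-square per gene at least 21.1), so all 13 were kept as separate samples.

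Each organ was fitted by itself with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the default filter on low counts, robust dispersions and the quasi-likelihood test, without covariates or a replicate block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference between organs was the interaction term of 1 edgeR model over all 13 libraries. Fold changes are log2 of vitrified over fresh with a standard error (SE) derived from the test statistic, and levels are CPM, computed from the estimated counts and the library totals, as mean ± SD. The version of edgeR offers 2 quasi-likelihood methods. Fits had first been viewed with the newer one, after which the installed default was used, since it is what the design fixed before the data were examined names, and the newer one is reported as an added alternative (0 calls in liver and 2 in kidney).

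Gene lists, 51 in all with 19 of cell type markers, 25 of functions, 1 of RNA quality and 6 related to sex, were fixed before the data were examined. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and the preset correlation of 0.01, adjusted over the lists of that organ. Camera with an estimated correlation and fry were alternatives. The lists for skeletal muscle, adrenal gland, exocrine pancreas and X inactivation had too few tested members in either organ.

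Genes were named by a rule that was also fixed in advance. It takes up to 8 genes per direction among those that pass, at a mean of at least 1 CPM and without overlap between groups, and fills a direction with fewer to 4 with the smallest p, given as not passing. It adds the 4 members with the smallest p of each called list, Y-linked genes, Igf2, Xist and H19 whatever their result, and the 8 genes with the smallest p of the organ difference. Predicted genes named Gm and a number are counted and not named by the rule, and Gm9008 is named because calls are few. Xist and H19 were not analysed here, and some genes that the rule gives are not reported here.

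The same steps were tested on simulated data with 200 changed genes. Of genes changed 2, 4 and 8 times, 7.46%, 77.6% and 97.0% were recovered in liver with 9 false calls, 10.4%, 82.1% and 93.9% in kidney with 14 false calls, and 10.4%, 46.3% and 84.8% for the organ difference with 4. A shifted circadian clock list was recovered in both organs with 0 other lists called. Genes were drawn independently of each other, so this simulation cannot show how often lists of correlated genes are called without a shift. The changed genes were drawn only from those above a minimum mean count, and libraries that stand apart were not simulated. Unchanged simulated genes had an unadjusted p under 0.05 by edgeR in 4.32% (liver) and 4.58% (kidney), against 3.16% and 2.05% of genes in the data. Recovery in the data can therefore be lower.

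The alternatives fixed in advance were DESeq2 1.42.0, its size factors in edgeR, library totals alone, no filter or a stricter filter on low counts, limma-voom with quality weights, 1 fit of all 13 libraries, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes at an FPKM of at least 1 in 3 libraries, the Y-linked level as a covariate for genes, and leaving out each library in turn. Others were added after seeing the data and are named as such. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.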

Results

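RNA sequencing was used to compare the livers and kidneys of CD-1 (ICR) mice, an outbred laboratory stock, at 8 weeks of age. The mice had developed from oocytes that were fertilised in vitro either fresh or after vitrification, a rapid freezing of the egg cell into a glass-like state from which it is later thawed. The 13 libraries fell into 4 groups, with 3 livers and 3 kidneys from fresh oocytes and 3 livers and 4 kidneys from vitrified oocytes. Estimated counts per library added up to between 16073251 and 19964914 over 22298 genes, of which 4011 had no count in any library. The labels call the libraries biological replicates and do not say whether a liver and a kidney of equal number came from the same mouse, or whether littermates were used.

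Transcripts of the Y chromosome set 3 libraries apart from the rest. They lay among the fresh but not the vitrified livers, and in both kidney groups, so the liver groups were not balanced in this respect. Summed over Ddx3y, Uty, Kdm5d and Eif2s3y, broadly expressed Y-linked genes, the level was 0.778 CPM in liver fresh 3, 1.25 CPM in kidney fresh 3 and 0.170 CPM in kidney vitrified 4, and lay between 137 and 205 CPM in the other 10 libraries. Liver fresh 3 also held 3071 CPM of A1bg and 7338 CPM of the cytochrome P450 gene Cyp3a41a, both on the fixed list of female-biased liver genes, where no other liver library exceeded 1.06 and 6.45 CPM. None of the 4 Y-linked genes differed between origins in either organ by edgeR's quasi-likelihood test (adjusted p at least 0.990). Ddx3y, for example, averaged 45.1 ± 38.8 CPM (SD, n = 3) in fresh and 74.8 ± 14.6 CPM (n = 3) in vitrified livers, and 43.1 ± 37.3 CPM (n = 3) and 46.5 ± 32.9 CPM (n = 4) in the kidneys. The imprinted growth factor gene Igf2 lay at or below 0.464 CPM in each of the 6 liver libraries. In the kidney it averaged 3.36 ± 5.01 CPM (n = 3) in the fresh and 17.4 ± 33.0 CPM (n = 4) in the vitrified group, because kidney fresh 3 held 9.15 CPM and kidney vitrified 4 held 66.9 CPM. Xist and H19 were not analysed here.

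Stress transcripts and transcripts of the other organ also set libraries apart. Hspa1a, an inducible heat shock chaperone, reached 57.3 CPM in liver vitrified 3 against at most 4.42 CPM in the other livers, and 438 CPM in kidney vitrified 3 against at most 50.8 CPM in the other kidneys. Alb, the albumin gene of hepatocytes, lay between 116 and 306 CPM in 5 kidney libraries but at 1.28 CPM in kidney vitrified 3 and 10.5 CPM in kidney vitrified 4. Kap, an abundant kidney transcript that like Alb was chosen after its values were seen, lay between 37.6 and 54.0 CPM in all 6 liver libraries.

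**Figure D1:**
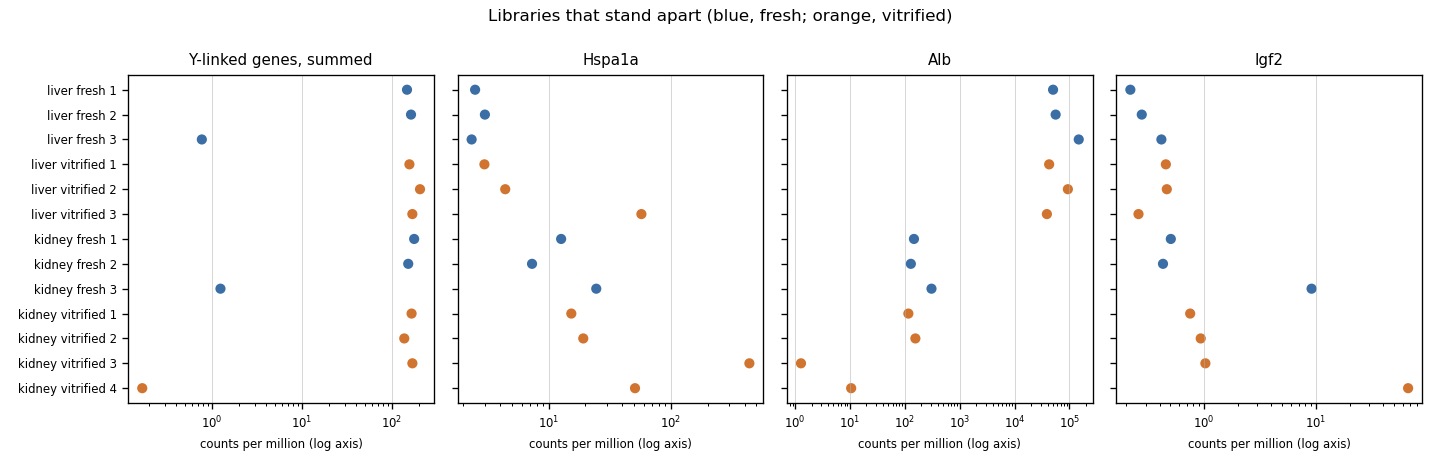
CPM values on log axes for the summed Y-linked genes, Hspa1a, Alb and Igf2, with 1 point per library and colours for oocyte origin. Liver fresh 3, kidney fresh 3 and kidney vitrified 4 lie at or below 1.25 CPM in Y-linked genes, and the highest Hspa1a level of each organ, 57.3 and 438 CPM, belongs to vitrified 3.

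The first comparison asked which liver transcripts differed between offspring of vitrified and of fresh oocytes, and no single liver gene passed the test. The genes nearest to it were lower in the vitrified group for Tpm3, a tropomyosin of the cytoskeleton (51.8 ± 18.4 against 10.5 ± 1.55 CPM, SD, n = 3 each), and for Retsat, which encodes retinol saturase (166 ± 32.2 against 66.8 ± 25.1 CPM). Ero1lb, an oxidase of the endoplasmic reticulum, averaged 48.4 ± 7.60 CPM in fresh and 19.3 ± 6.48 CPM in vitrified livers. Among genes that were higher in the vitrified group, Pkd2, which encodes polycystin 2, averaged 7.18 ± 3.10 against 2.31 ± 0.414 CPM.

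Of 12335 liver genes tested with edgeR, 0 reached an adjusted p under 0.05, and 390 had an unadjusted p under 0.05 (3.16% of those tested, where 5% is expected with no difference), 213 higher and 177 lower in the vitrified group. The smallest adjusted p was 0.858, for Tpm3 (ENSMUSG00000027940), whose log2 fold change was -2.24 ± 0.31 (SE). None of the genes that the naming rule gave passed. They also included Pkd2 (ENSMUSG00000034462, 1.67 ± 0.35), the general transcription factor gene Gtf2a2 (ENSMUSG00000033543, 0.77 ± 0.17), the glutathione transferase gene Gsta2 (ENSMUSG00000057933, 1.15 ± 0.28), Retsat (ENSMUSG00000056666, -1.29 ± 0.27), Ero1lb (ENSMUSG00000057069, -1.28 ± 0.27) and Prxl2b (ENSMUSG00000029059, -1.08 ± 0.23). DESeq2 called 10 liver genes, among them Tpm3, Pkd2, Retsat and the fatty acid hydroxylase genes Cyp4a14 and Cyp4a31. Limma-voom called 1 (Gm9008) and limma on log2(FPKM + 1) called 0. Tpm3 shares sequence with a near-identical copy, Tpm3-rs7, so the counts of both are uncertain, as are those of Gm9008, which shares 0.629 of its 50-base words with Gm49380. Summed over Tpm3 and Tpm3-rs7 the liver held 56.0 ± 12.3 CPM (SD) in the fresh and 42.8 ± 2.22 CPM in the vitrified group. The values of the groups did not overlap for 935 liver genes, 7.58% of those tested, where chance gives 10%.

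Of 44 gene lists tested in the liver, fixed before the data were examined, 14 had an adjusted p under 0.05 by camera with its preset correlation, 7 higher and 7 lower in the vitrified group. None of these 14 calls held with an estimated correlation, where the adjusted p was 0.815 for 9 of them and 0.855 for heat shock proteins, cholesterol synthesis, male-biased genes, cell cycle and interferon response. In all 14 lists 0 members passed over all genes tested and 0 adjusted over the list alone. The median, the mean and the test had the same sign in each. Each call held in the fits without 1 library that are not named below.

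Cytosolic ribosomal protein genes, the list fixed as a sign of RNA quality, were higher as a group, with 30 of 31 members above 0, a median log2 fold change of 0.27 and a camera adjusted p of 9.09e-08 (adjusted p = 0.815 with an estimated correlation). Their members with the smallest p were Rps27 (0.52 ± 0.18, SE), Rpl27 (0.43 ± 0.18), Rps18 (0.54 ± 0.24) and Rps16 (0.39 ± 0.19). Extracellular matrix genes were lower, with 3 of 20 above 0 and a median of -0.38 (adjusted p = 0.815 with an estimated correlation). Among them were the collagen genes Col1a1 (-1.18 ± 0.44) and Col1a2 (-0.80 ± 0.30), the elastin gene Eln (-1.22 ± 0.44) and Sparc (-0.74 ± 0.27). Without liver fresh 3 the log2 fold change was 0.727 of this value for Col1a1 and 0.609 of it for Col1a2. Markers of stellate cells and fibroblasts lay below 0 in 11 of 13 members (median -0.21) and were not called (camera adjusted p = 0.0895). The ribosomal and matrix calls held in each of the 6 fits that left out 1 liver library. The ribosomal call was weakest without liver fresh 1 (camera adjusted p = 0.00319) and the matrix call without liver vitrified 1 (0.0481).

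Genes of fatty acid oxidation and targets of the fat-sensing receptor PPAR alpha were lower in the vitrified livers, with 0 of 22 members above 0 and a median log2 fold change of -0.52 (adjusted p = 0.815 with an estimated correlation). Cyp4a14 had a log2 fold change of -6.45 ± 1.82, Cyp4a10 of -4.58 ± 1.85, the pantetheinase gene Vnn1 of -2.96 ± 1.03 and Hadha, of mitochondrial beta-oxidation, of -0.50 ± 0.22. Cyp4a14 lay at 246 CPM in liver fresh 3, the library near 0 in Y-linked counts, and at or below 17.9 CPM in the other livers. Without it the call of the list was lost (camera adjusted p = 0.212), as it was with the Y-linked level as a covariate (0.325). Bile acid genes were also lower (3 of 18 above 0, median -0.21; adjusted p = 0.815 with an estimated correlation). The values were -0.80 ± 0.36 for the bile salt export pump gene Abcb11, -0.45 ± 0.20 for Abcc2, 0.34 ± 0.21 for Baat and -0.35 ± 0.23 for Abcg8. That call was lost without liver fresh 2 (adjusted p = 0.0617), liver vitrified 2 (0.0940) or liver vitrified 3 (0.0754).

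Immediate early genes, which cells switch on within minutes of a stimulus, were higher, with 14 of 14 members above 0 and a median of 1.39 (adjusted p = 0.815 with an estimated correlation). Zfp36 had a log2 fold change of 1.36 ± 0.38, Klf2 of 1.34 ± 0.44, Egr1 of 3.78 ± 1.51 and Btg2 of 3.42 ± 1.46. Heat shock protein genes were higher in 14 of 15 members (median 1.05; adjusted p = 0.855 with an estimated correlation), among them Hspa1a (3.22 ± 1.37), Hspa1b (3.50 ± 1.54), Dnajb1 (2.64 ± 1.34) and Bag3 (1.82 ± 0.94). So were 20 of 23 genes of cholesterol synthesis and uptake (median 0.49; adjusted p = 0.855 with an estimated correlation). Stard4 was at 0.72 ± 0.31, Msmo1 at 1.20 ± 0.56 and Sqle at 1.39 ± 0.78. Liver vitrified 3 held 198 CPM of Egr1, against at most 16.1 CPM in the other 5 livers. Without it the camera adjusted p was 0.0669 for immediate early genes, 0.0879 for heat shock proteins with the opposite direction, and 0.515 for cholesterol synthesis with the opposite direction. The cholesterol call was also lost without liver fresh 1 (0.744).

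The sex-linked lists differed in the direction of liver fresh 3. Female-biased liver genes were lower in the vitrified group in 11 of 12 members, with a median log2 fold change of -4.89 (camera adjusted p = 0.00141, and adjusted p = 0.815 with an estimated correlation). They included Cyp17a1 (-3.03 ± 1.11), Cyp3a41b (-11.80 ± 4.21), Cyp3a41a (-9.62 ± 3.64) and A1bg (-10.17 ± 3.89). Male-biased genes (12 of 19 above 0, median 0.20; adjusted p = 0.855 with an estimated correlation) and Y-linked genes (4 of 4 above 0, median 0.70; adjusted p = 0.815 with an estimated correlation) were higher. Of the male-biased genes, Slco1a1 had a log2 fold change of -0.44 ± 0.24, Mup3 of 0.32 ± 0.27, Mup20 of 1.299 ± 1.397 and Nudt7 of 0.26 ± 0.36. Without liver fresh 3 the adjusted p was 0.992 for female-biased and 0.349 for Y-linked genes, and the male-biased list was called in the opposite direction (0.0409). With the Y-linked level as a covariate, a setting chosen after seeing the data, the direction turned for female-biased (0.945) and for male-biased genes (0.0117). The Y-linked call was lost as well without liver vitrified 1, 2 or 3 (0.0860, 0.0940 and 0.0634), and the male-biased call without liver vitrified 1 (0.0659) or 3 (0.284).

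Cell cycle genes (15 of 18 below 0, median -0.67) and interferon response genes (19 of 25 below 0, median -0.31) were lower as groups, and with an estimated correlation the adjusted p was 0.855 for both. The kinesin gene Kif20a had a log2 fold change of -2.33 ± 0.90, Aurka of -0.96 ± 0.44, Cdk1 of -1.05 ± 0.57 and Ccnb2 of -1.77 ± 0.95. Of the interferon genes, Ifi44 had -1.11 ± 0.48, Ifi27l2a -1.35 ± 0.58, Usp18 -0.73 ± 0.34 and Cxcl10 3.76 ± 1.77. Without liver fresh 3 both lists turned to the opposite direction, with camera adjusted p of 0.251 and 0.992, as they did with the Y-linked covariate (0.151 and 0.945). The cell cycle call was lost too without liver vitrified 1 (0.130) or 2 (0.0622), and the interferon call without liver fresh 2 (0.0912), liver vitrified 1 (0.0929) or liver vitrified 2 (0.405). Neutrophil and monocyte genes were higher (5 of 7 above 0, median 1.07; adjusted p = 0.815 with an estimated correlation). S100a9 was at 2.19 ± 0.76, S100a8 at 2.78 ± 0.97, Retnlg at 1.76 ± 0.82 and Csf3r at 0.61 ± 0.34. The neutrophil call was lost without liver fresh 1 (0.402), liver fresh 2 (0.0617) or liver vitrified 2 (0.309). Markers of the proximal tubule of the kidney, some of which the liver expresses too, such as Slc27a2 at 1068 CPM in the fresh group, were lower as a group (14 of 18 below 0, median -0.23; adjusted p = 0.815 with an estimated correlation). Acsm2 was at -0.62 ± 0.23, Lrp2 at -0.55 ± 0.24, Slc5a2 at -0.81 ± 0.43 and Slc22a8 at -1.02 ± 0.56. That call was lost without liver fresh 2 (0.0689) or liver vitrified 1 (0.147). Slc34a1, another member, lay at a trace of its kidney level, at 4.9 to 8.5 CPM in the livers against 3212 CPM or more in the kidneys. Whether kidney RNA or reads were carried into the liver libraries was not tested.

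**Figure D2:**
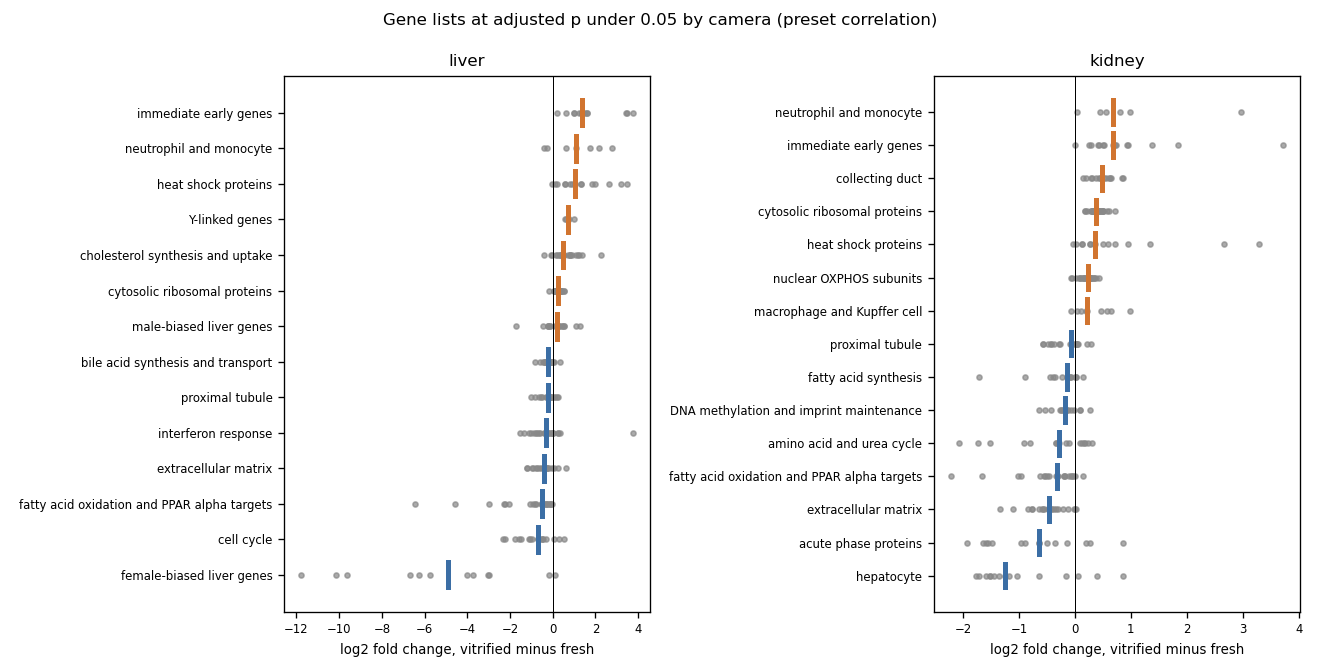
Log2 fold changes (vitrified minus fresh, horizontal axis) of the members of each gene list at a camera adjusted p under 0.05 with the preset correlation, 14 in liver and 15 in kidney. Grey points are genes and a bar stands for the list median in orange where the list was higher and blue where it was lower. The widest shift is that of female-biased genes in liver, with a median of -4.89, which was lost without liver fresh 3. With an estimated correlation 0 lists were called in either organ (smallest adjusted p 0.815 and 0.638).

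The second comparison asked the same of the kidney, where again no gene passed by edgeR, though several came closer than in liver. Lbp, which encodes a plasma protein that binds bacterial lipopolysaccharide, averaged 17.5 ± 8.84 CPM (SD, n = 3) in fresh and 3.34 ± 1.20 CPM (n = 4) in vitrified kidneys, and Prxl2b, a prostaglandin F synthase gene, averaged 25.1 ± 5.23 and 5.75 ± 2.50 CPM. The collagen gene Col8a1 averaged 16.1 ± 4.63 CPM in fresh and 7.06 ± 1.997 CPM in vitrified kidneys. In the other direction, Atp9a, which encodes a lipid-transporting ATPase, averaged 36.7 ± 4.56 CPM in fresh and 66.5 ± 8.43 CPM in vitrified kidneys.

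Of 14018 kidney genes tested with edgeR, 0 had an adjusted p under 0.05, and 288 had an unadjusted p under 0.05 (2.05% of those tested), 137 higher and 151 lower in the vitrified group. The smallest adjusted p was 0.0535, shared by Gm9008, a predicted gene at 0.0175 ± 0.0303 CPM (SD) in fresh and 2.72 ± 0.357 CPM in vitrified kidneys (adjusted p from 4.22e-05 to 0.902 over alternatives), and by Bglap3 (ENSMUSG00000074489), an osteocalcin-related gene with 0.0386 ± 0.0336 CPM (SD) in fresh and 2.66 ± 0.922 CPM in vitrified kidneys (adjusted p from 6.54e-05 by DESeq2 to 0.902 over 20 alternatives). The rule also named Atp9a (ENSMUSG00000027546, log2 fold change 0.88 ± 0.17, SE) and the signalling gene Wnt4 (ENSMUSG00000036856, 1.76 ± 0.42) in the higher direction. In the lower direction it named Lbp (ENSMUSG00000016024, -2.37 ± 0.37), Prxl2b (-2.12 ± 0.34) and Col8a1 (ENSMUSG00000068196, -1.19 ± 0.23), and none of these passed. DESeq2 called 11 kidney genes, among them Lbp, Prxl2b, Bglap3, Atp9a, Col8a1 and Ero1lb. Limma-voom called 4, among them Prxl2b, Gm9008 and Bglap3, and limma on log2(FPKM + 1) called 0. The values of the groups did not overlap for 403 kidney genes, 2.87% of those tested, where chance gives 5.71%. Leaving out kidney fresh 1 gave 3 calls by edgeR, Lbp, Tpm3-rs7 and AK157302.

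Of 41 gene lists tested in the kidney, 15 had an adjusted p under 0.05 by camera with its preset correlation, 7 higher and 8 lower, and none held with an estimated correlation. With it the adjusted p was 0.822 for nuclear OXPHOS subunits and heat shock proteins, 0.678 for ribosomal proteins, immediate early genes, macrophages, proximal tubule and DNA methylation, and 0.638 for the other 8. In all 15 lists 0 members passed over all genes tested and 0 adjusted over the list alone. The median, the mean and the test had the same sign in each of them. Among the lists that were not called, that of stellate cells and fibroblasts (camera adjusted p = 0.157) was 1 of 2 with a member that passed adjusted over the list alone, the reelin gene Reln (-0.91 ± 0.21). Without kidney fresh 3 and kidney vitrified 4, the libraries near 0 in Y-linked counts, 8 lists were called. The camera adjusted p was then 0.105 for hepatocyte and for neutrophil markers, 0.115 for the proximal tubule, 0.142 for fatty acid synthesis, 0.159 for acute phase proteins and for fatty acid oxidation, 0.160 for macrophages and 0.431 for amino acid genes. With the Y-linked level as a covariate it was 0.0568 for amino acid genes, 0.0637 for DNA methylation and 0.0647 for neutrophils, and without a filter on low counts 0.700 for macrophages and 0.0798 for the proximal tubule. Both settings with Y-linked counts were chosen after seeing the data.

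Cytosolic ribosomal protein genes, fixed as a sign of RNA quality, were higher in 31 of 31 members (median log2 fold change 0.38, camera adjusted p = 1.88e-08, and adjusted p = 0.678 with an estimated correlation). Rps20 was at 0.71 ± 0.33, Rps9 at 0.58 ± 0.31, Rpl18 at 0.46 ± 0.25 and Rplp0 at 0.51 ± 0.28. Nuclear genes for subunits of oxidative phosphorylation were higher in 25 of 27 (median 0.24; adjusted p = 0.822 with an estimated correlation). Sdhc was at 0.35 ± 0.21, Ndufs3 at 0.34 ± 0.22 and Cox4i1 at 0.38 ± 0.31. The OXPHOS call was lost without kidney fresh 2 (0.0567) or kidney vitrified 2 (0.581). Extracellular matrix genes were lower, with 2 of 21 above 0 and a median of -0.47 (adjusted p = 0.638 with an estimated correlation). Col1a1 had a log2 fold change of -1.34 ± 0.44, Col3a1 of -1.10 ± 0.44, Col15a1 of -0.77 ± 0.30 and Col1a2 of -0.76 ± 0.31. Markers of stellate cells and fibroblasts lay below 0 in 9 of 12 members (median -0.21) and were not called (camera adjusted p = 0.157). Both calls, ribosomal and matrix, held in each of the 7 fits that left out 1 kidney library. The ribosomal call was weakest without kidney vitrified 2 (camera adjusted p = 0.00297) and the matrix call without kidney fresh 3 (0.00260). Of the vitrified kidneys, kidney vitrified 2 had the highest mean level of the ribosomal list and the lowest of the matrix list (8.21 and 3.57 as log2(CPM + 1)), so it adds to both shifts.

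Among nephron markers, those of the collecting duct were higher in 14 of 14 members (median 0.49; adjusted p = 0.638 with an estimated correlation). They included the anion exchanger gene Slc26a4 (0.85 ± 0.30), the proton pump genes Atp6v0d2 (0.65 ± 0.28) and Atp6v1g3 (0.62 ± 0.34), and Fxyd4 (0.86 ± 0.39). Proximal tubule markers were lower in 11 of 18 (median -0.08; adjusted p = 0.678 with an estimated correlation). They included the endocytic receptor genes Cubn (-0.57 ± 0.23) and Lrp2 (-0.47 ± 0.22), Slc5a12 (-0.57 ± 0.34) and Keg1 (-0.36 ± 0.26). The proximal tubule call was lost without kidney fresh 1 (0.233), kidney fresh 3 (0.05004), kidney vitrified 3 (0.101) or kidney vitrified 4 (0.337). The collecting duct call held in each of the 7 fits that left out 1 kidney library (highest camera adjusted p 0.0267). Without kidney vitrified 3 and 4, an alternative chosen after seeing the data, the camera adjusted p was 0.103 for the collecting duct and 0.819 for the proximal tubule.

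Hepatocyte markers were lower in the vitrified kidneys (12 of 15 below 0, median -1.25; adjusted p = 0.638 with an estimated correlation), and so were acute phase genes (12 of 15 below 0, median -0.65; adjusted p = 0.638 with an estimated correlation). The transferrin gene Trf had a log2 fold change of -1.03 ± 0.47, Serpina1a of -1.25 ± 0.61, Apoa2 of -1.18 ± 0.68 and the fibrinogen gene Fga of -0.64 ± 0.44. Among acute phase genes C3 had -0.89 ± 0.32, Orm1 -1.92 ± 1.03, Hp -1.48 ± 0.79 and Hpx -1.64 ± 1.09. Amino acid and urea cycle genes were lower as well (11 of 17 below 0, median -0.29; adjusted p = 0.638 with an estimated correlation). Otc was at -2.07 ± 0.99, Arg1 at -1.73 ± 1.03, Gls2 at -0.92 ± 0.60 and Psat1 at -0.29 ± 0.16. Alb was lowest in kidney vitrified 3 and 4 (1.28 and 10.5 CPM), and without both libraries the camera adjusted p was 0.103 for hepatocyte, 0.117 for acute phase and 0.476 for amino acid genes, 0.151 for fatty acid oxidation, 0.507 for fatty acid synthesis, 0.819 for immediate early genes, 0.379 for macrophages and 0.328 for neutrophils. Heat shock proteins then had the opposite direction (0.973). The amino acid call was lost without kidney fresh 3 (0.161), kidney vitrified 3 (0.0853) or kidney vitrified 4 (0.177). The hepatocyte and acute phase calls held in each of the 7 fits that left out 1 kidney library (highest camera adjusted p 0.00519 and 0.0451).

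Fatty acid oxidation genes were lower in 19 of 21 members (median -0.32; adjusted p = 0.638 with an estimated correlation). Plin2 was at -0.97 ± 0.52, the receptor gene Ppara at -0.56 ± 0.31 and Acadm at -0.53 ± 0.30. The oxidation call was lost without kidney fresh 3 (0.177). Fatty acid synthesis genes were lower in 11 of 15 (median -0.14; adjusted p = 0.638 with an estimated correlation). The desaturase gene Scd1 was at -1.71 ± 0.80, Fasn at -0.44 ± 0.25, Elovl6 at -0.88 ± 0.67 and Gpam at -0.36 ± 0.32. That call was lost without kidney fresh 2 (0.104), kidney fresh 3 (0.137), kidney vitrified 3 (0.0918) or kidney vitrified 4 (0.193). Genes of DNA methylation and imprint maintenance were lower in 13 of 16 (median -0.17; adjusted p = 0.678 with an estimated correlation). Hells was at -0.54 ± 0.38, Mbd3 at 0.27 ± 0.20, Tet1 at -0.65 ± 0.55 and the methyltransferase gene Dnmt3a at -0.24 ± 0.23. The methylation call was lost without kidney fresh 2 (0.0941), kidney fresh 3 (0.131), kidney vitrified 1 (0.0766) or kidney vitrified 2 (0.463). Imprinted genes themselves had a median of -0.17 with 7 of 27 above 0 and a camera adjusted p of 0.148 (0.961 in liver), and the circadian clock list one of 0.983 (0.608 in liver).

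Immediate early genes were higher in 15 of 15 members (median 0.68; adjusted p = 0.678 with an estimated correlation). Klf2 was at 0.72 ± 0.25, Atf3 at 3.72 ± 1.51, Nr4a1 at 1.37 ± 0.74 and Fosb at 1.84 ± 1.04. Heat shock proteins were higher in 14 of 15 (median 0.36; adjusted p = 0.822 with an estimated correlation). Hspa1a was at 3.28 ± 1.42, Dnajb1 at 1.35 ± 0.71, Hspa1b at 2.67 ± 1.48 and Hspb1 at 0.96 ± 0.56. Without kidney vitrified 3 the camera adjusted p was 0.386 for immediate early genes and 0.617, with the opposite direction, for heat shock proteins, whose call was also lost without kidney fresh 3 (0.0870). Macrophage markers were higher in 8 of 9 (median 0.22; adjusted p = 0.678 with an estimated correlation). Lyz2 was at 0.58 ± 0.26, the complement genes C1qb at 0.64 ± 0.30 and C1qa at 0.47 ± 0.30, and Aif1 at 0.98 ± 0.52. The macrophage call was lost without kidney fresh 2 (0.255) or kidney vitrified 4 (0.400). Neutrophil and monocyte markers were higher in 6 of 6 (median 0.69; adjusted p = 0.638 with an estimated correlation). S100a9 was at 2.98 ± 0.92, Csf3r at 0.99 ± 0.59, Ltf at 0.81 ± 0.76 and Mmp9 at 0.56 ± 0.69. The neutrophil call was lost without kidney fresh 3 (0.0648), kidney vitrified 3 (0.0823) or kidney vitrified 4 (0.151).

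**Figure D3:**
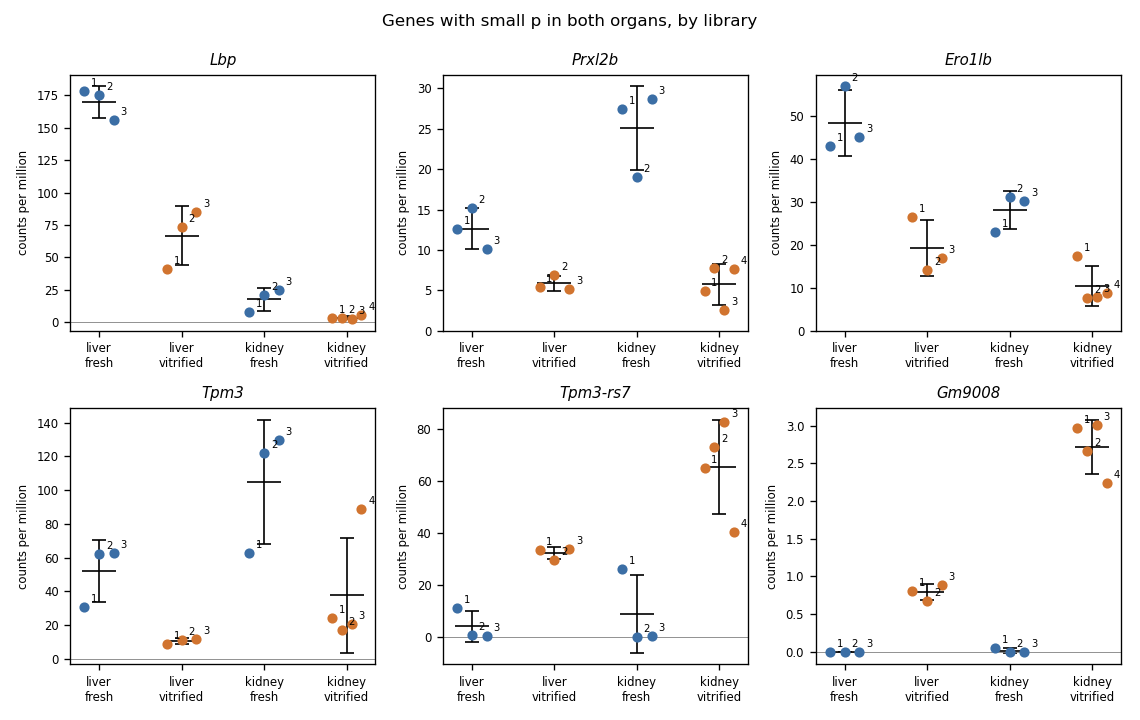
CPM values of 6 genes in each library, with the replicate number beside each point and black lines for the mean and SD of each group. Lbp, Prxl2b and Ero1lb do not overlap between origins in either organ, and Tpm3-rs7 lies between 29.7 and 82.6 CPM in the 7 vitrified libraries.

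The last comparison asked whether the 2 organs shared their differences, and several genes had small p-values in both with the same sign. Lbp had a log2 fold change of -1.29 in liver and -2.37 in kidney, Prxl2b of -1.08 and -2.12, and Ero1lb of -1.28 and -1.41. These genes were singled out after their values were seen. Collagen genes lay among them too, with Col1a1 at -1.18 in liver and -1.34 in kidney, though without liver fresh 3 the liver values of Col1a1, Col1a2 and Col5a2 came to 0.727, 0.609 and 0.571 of their size. So did the neutrophil gene S100a9 at 2.19 and 2.98. Tpm3-rs7, the copy of Tpm3, lay at 11.2 CPM in liver fresh 1 and 26.2 CPM in kidney fresh 1 and at or below 0.765 CPM in the other fresh libraries, against 29.7 to 82.6 CPM in the vitrified ones. Tpm3 itself was lower in both organs, and summed over both copies the kidneys held 114 ± 21.9 CPM (SD) in the fresh and 103 ± 18.7 CPM in the vitrified group. Of 11997 genes tested in both organs, 39 had an unadjusted p under 0.05 in each, 18 higher and 20 lower in both and 1 with opposite signs, where independent lists would share 3.29 in the same and 3.31 in opposite directions. These values take the organs as independent, and chance could not be excluded when libraries of equal number were moved together, as 15 of 35 splits gave as many genes with the same sign (28 by limma for the real split, 166 for the highest other). Across these genes the fold changes of the organs correlated with Pearson's r = 0.355 and Spearman's rho = 0.369, a description across genes, which are not independent replicates.

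No gene was called as differing between the organs in its change from fresh to vitrified. In the simulation 10.4% of 2-fold and 46.3% of 4-fold organ differences were recovered, so such differences can be missed. By the interaction term in edgeR, 0 of 14441 genes had an adjusted p under 0.05 and 275 had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0, with 313 and 451 genes at an unadjusted p under 0.05. The 8 genes with the smallest p that the rule named, none of which passed (adjusted p = 0.9999 for each), had differences of log2 fold changes, liver minus kidney, of -2.57 ± 0.48 (SE) for Afap1l2, -2.90 ± 0.57 for Plcl1, 2.92 ± 0.68 for the alcohol dehydrogenase gene Adh4, -5.84 ± 1.33 for Dmrt2, 1.45 ± 0.35 for Fmn1, 4.40 ± 1.07 for the adrenergic receptor gene Adrb3, 1.18 ± 0.29 for Micu3 and 2.35 ± 0.60 for the apolipoprotein gene Apoc2. Of the gene lists, 7 were called in both organs by camera, all in the same direction: ribosomal proteins, immediate early genes, heat shock proteins and neutrophil and monocyte genes higher, and extracellular matrix, fatty acid oxidation and proximal tubule genes lower. None of the 7 held with an estimated correlation, where the adjusted p was 0.815 or 0.855 in liver and 0.638 to 0.822 in kidney. In each organ the immediate early and heat shock calls were lost without vitrified 3, and the fatty acid oxidation call without fresh 3. The neutrophil and proximal tubule calls were lost in several fits. Of these 7 lists, only the ribosomal and matrix calls held in each fit without 1 library of either organ. How many lists both organs share by chance when libraries of equal number move together was not counted.

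**Figure D4:**
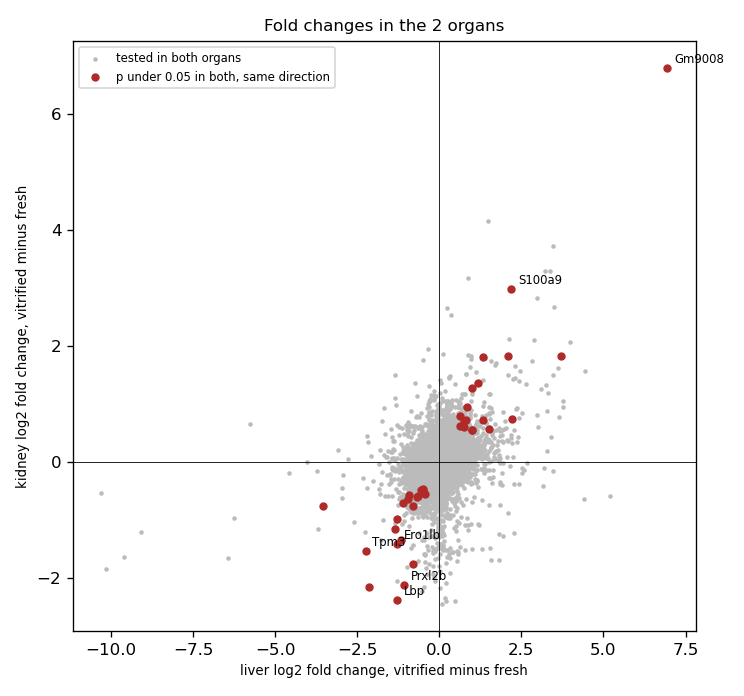
Log2 fold change, vitrified minus fresh, of 11997 genes in liver (horizontal axis) and kidney (vertical axis), with the genes at an unadjusted p under 0.05 and the same sign in both organs in red. The 38 red genes lie in the upper right and lower left quadrants, and the correlation across all points is 0.355. The fitted fold of Gm9008, at the upper right, rests on almost no counts in the fresh groups and depends on the prior count.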

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

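The tests on which libraries carry liver transcripts, on the first component of the kidney libraries and on the sex and kinship of the animals were chosen only after the result was seen, while the counts over other splits of the libraries and the test on near-identical copies were planned. In the kidney vitrified group, the only group of 4, 85 levels were examined for 1 library far from the other 3. In all 10 were found, with 5 in kidney vitrified 3, 4 in kidney vitrified 4 and 1 in kidney vitrified 2. A rate of 1 in 20 would give 4.25, but that rate holds for independent levels with a normal spread. Most of these levels were genes or lists picked by their p in the same data, and some overlap, as Hspa1a and the heat shock list do. The count therefore cannot show whether there is an excess over chance. Kidney vitrified 3 lay above the other 3 in Atf3 (48.7 CPM), Hspa1a (438 CPM), Hspa1b (511 CPM), Dnajb1 (156 CPM) and the mean level of the heat shock list (8.32 as log2(CPM + 1)). Kidney vitrified 4 lay above the others in Elovl6 (45.1 CPM), Igf2 (66.9 CPM) and the mean level of the collecting duct list (6.01), and below them in Acadm (663 CPM). Kidney vitrified 2 lay above the others in Sdhc (273 CPM).

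Kidney fresh 3 and kidney vitrified 4 lay apart from the other kidneys on the first component of variation, which held 42.9% of the variance (52.3 and 74.5 against -21.1 to -27.9). A batch marked by the loss of liver transcripts is argued against as the source of this component. The reason is that Alb was at 306 CPM in kidney fresh 3, the highest of the 7 kidneys. The sex of the animals may underlie the component, since both libraries were near 0 in Y-linked counts, and 77.8% of 27 members of the sex-biased kidney lists had a loading of the predicted sign, between the bounds set for and against. The labels give no sex. Such low Y-linked levels are those that female animals would give, but whether sex underlies the component stays open as a hypothesis. On the second component (20.5% of the variance) kidney vitrified 3 and 4, the libraries low in Alb, lay at -57.6 and -23.5. The other kidneys lay at 6.59 to 31.2. Whether these 2 libraries, both of the vitrified group, form a batch was not tested.

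Liver transcripts in kidney libraries were the second pattern, with Alb between 116 and 306 CPM in 5 kidneys and at 1.28 and 10.5 CPM in kidney vitrified 3 and 4. Liver RNA or liver reads carried into the 5 libraries is a candidate explanation, as the median number of the 50 most abundant liver genes under 0.05% of their liver level was 0 in them, against 28 and 29 genes in kidney vitrified 3 and 4. Expression by kidney cells that was lost after vitrification was left undecided by the mean level of the hepatocyte list. For that level, 1 vitrified library lay within the range of the fresh kidneys and the other 3 below it. The bound of that test was changed after this value was known, and by the bound before, the loss was argued against. Kidney vitrified 1 and 2 held the 50 genes at a median of 0.198% and 0.245% of their liver level. Kidney fresh 1, 2 and 3 held them at 0.242%, 0.207% and 0.588%. These values argue against such a loss in kidney vitrified 1 and 2. In kidney vitrified 3 and 4, at 0.0255% and 0.0198%, a loss cannot be told apart from an absence of carry-over by these levels. In the other 5 kidneys each of the 50 genes lay at 0.0904% or more of its liver level, which is what carry-over would give. The tests of carry-over, of kidney expression and of a batch replaced earlier ones after those had been run. The reason was that the hepatocyte list holds genes that the kidney expresses, 8 of 15 at 1 CPM or more in kidney vitrified 3. The earlier carry-over test, on the spread of kidney to liver ratios over that list, had come out against carry-over (median SD 2.76 on the log2 scale), so the verdict turned with the choice of test, while on the summed list the test of kidney expression was undecided and that of a batch came out against it, as the later one did (1560.5 CPM in kidney fresh 3).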

How the results depend on the processing

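The alternatives without the libraries near 0 in Y-linked counts, without kidney vitrified 3 and 4, with the Y-linked level as a covariate in list tests and with the newer quasi-likelihood method were chosen only after the data were seen. In liver, DESeq2 called 10 genes, limma-voom 1, fits leaving out 1 library 0 to 1 (1 without liver fresh 1), and an unadjusted p with a 2-fold change 154, against 0. In kidney, DESeq2 called 11, limma-voom 4, no filter 2, a stricter filter 2, the Y-linked covariate 2, the newer quasi-likelihood method 2, the fit of all 13 libraries 1, fits leaving out 1 library 0 to 3 (3 without kidney fresh 1), and an unadjusted p with a 2-fold change 123. The organ difference gave 226 genes by an unadjusted p and a 2-fold difference and 0 by the other alternatives. The number of lists called in liver, 14, became 0 with an estimated correlation and 0 by fry in either form, and 8 to 15 without 1 library (8 without liver vitrified 3). The number in kidney, 15, became 0 with an estimated correlation and 0 by fry in either form, 8 without the libraries near 0 in Y-linked counts (7 of them among the 15), 6 without kidney vitrified 3 and 4 (4 of them among the 15), and 10 to 19 without 1 library. The organ correlation of 0.355 was 0.412 without the libraries near 0 in Y-linked counts and 0.231 to 0.373 without 1 library. In liver the direction reversed (camera adjusted p) without liver vitrified 3 for cholesterol synthesis (0.515) and heat shock proteins (0.0879), without liver fresh 3 for interferon response (0.992), cell cycle (0.251) and male-biased genes (0.0409), and with the Y-linked covariate for interferon response (0.945), cell cycle (0.151), Y-linked (0.945, fixed by the covariate itself), male-biased (0.0117) and female-biased genes (0.945). In kidney it reversed for heat shock proteins without kidney vitrified 3 (0.617) and without kidney vitrified 3 and 4 (0.973). Without 1 library, these lists ranged from 2.09e-07 to 0.744 (cholesterol), 1.52e-05 to 0.0879 (heat shock in liver), 7.01e-08 to 0.992 (interferon), 5.84e-06 to 0.251 (cell cycle), 2.39e-06 to 0.284 (male-biased) and 0.00236 to 0.617 (heat shock in kidney). The cause was not tested. Of 1115 further fits of 64 named liver genes 1099 kept direction and call, 5 passed the threshold and 11 differed in sign uncalled, and of 1425 of 73 kidney genes 1385, 15 and 25 did. Annotation terms were not run because the table carries no GO or KEGG terms.

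With the replicate number as a block, 0 genes were called in liver, kidney and the organ difference, and 16 lists in liver and 17 in kidney. The block ended the kidney calls of macrophages (0.439), amino acid genes (0.145), the proximal tubule (0.306), neutrophils (0.145) and fatty acid synthesis (0.179). The numbers were not taken as pairing fresh with vitrified libraries, whose deviations correlated at 0.050005, -0.168 and -0.0623 in liver and 0.276, -0.0296 and -0.405 in kidney, nor the organs, where same-numbered pairs gave 0.0154 to 0.336. As a hint from the data, 5 of 6 liver libraries correlated best with the kidney library of their own number and origin.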

Other observations

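The tests on sex, kinship and copies below were run on genes found with the same sign in both organs, and those on sex and kinship and the list of nerve genes were chosen only after the result was seen. Kidney vitrified 4 also had the highest mean level of the interferon response list, 5.03 as log2(CPM + 1), against 3.895 in kidney fresh 3 and at most 3.21 in the other 5 kidneys, and its antigen presentation list summed to 2337 CPM against at most 935 CPM. Liver vitrified 3 held 430 CPM of the acute phase gene Saa1 and 298 CPM of Saa2, against at most 127 and 53.8 CPM in the other livers, along with 122 CPM of Lcn2. Liver fresh 3 held 25.8 CPM of the proliferation gene Mki67, where the other livers held at most 4.02 CPM. These are values of single libraries and were not tested between origins.

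Genes of peripheral nerve, a list chosen after seeing the data, summed to 10.997 and 13.3 CPM in kidney fresh 1 and 2 and to between 31.9 and 46.2 CPM in the other 5 kidneys. Among them Nefl lay at 0.252 and 0.123 CPM in those 2 kidneys and between 2.31 and 4.52 CPM in the others. Of the fixed sex-biased kidney genes, 2 that were chosen after their values were seen set kidney fresh 3 and kidney vitrified 4 apart. Cyp2j13 lay at 2.34 and 0.736 CPM there and at 505 CPM or more elsewhere, and Slc7a12 at 288 and 66.5 CPM against at most 2.80 CPM.

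Genes with the same sign in both organs were the third pattern, 38 with an unadjusted p under 0.05 in each, of which 14 did not overlap between origins in either organ. Chance could not be excluded: moving equal numbers of both organs together, 15 of 35 splits gave as many such genes by limma (28 for the real split, 166 for the highest other), and 9 of 35 gave as high a correlation of fold changes (0.276 and 0.329). Without the 3 libraries near 0 in Y-linked counts, 29 of the 38 kept their sign and 0.8 or more of their fold change in both organs. The median share kept over the shared genes was 0.987 in liver and 1.08 in kidney. These values argue against sex, as marked by Y-linked counts, as the source of the shift in those 29 genes, and it stays open for the rest. A gene that follows sex could hardly enter the 38, as 0 of 47 genes of the fixed sex lists tested in both organs did. Near-identical copies as the main cause are argued against, as 21.1% of the 38 shared 0.2 or more of their 50-base words with another gene, though in 300 random genes it was 7.33%. Heritable differences between the outbred animals may be involved and cannot be told apart from vitrification, since the labels give no families. Same-numbered libraries of both organs deviated together over these genes, with a mean correlation of 0.449 against -0.177 in other pairs of the same origin. Centring within each group pushes the other pairs below 0, so the difference of 0.626 is inflated. If equal numbers mark the same mouse, any difference between mice that both organs share would give this too. The test therefore cannot decide for heritable differences, and an effect of vitrification itself stays open.

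Other splits of the libraries were also counted for the results of each organ. For genes called they tell nothing about chance, since the real split called 0 and each split then calls as many: 10 of 10 in liver (highest other 1), 35 of 35 in kidney (highest other 103) and 30 of 30 drawn relabellings for the organ difference (highest other 3). At an unadjusted p under 0.05, a count added after the results were seen, the real split gave 288 kidney genes against a median of 478 over the 35 splits, and chance could not be excluded (21 of 35 gave as many, highest other 2785). In liver it gave 390 against a median of 493.5 (highest other 865), with too few splits for a share under 0.05. For lists, the 10 splits in liver are too few for a share under 0.05. The real split called 14 lists, against a median of 14.5 over the splits (19 for the highest other, 8 with as many). In kidney chance could not be excluded for lists, with 22 of 35 splits calling as many. There the real split called 15, against a median of 16 (19 for the highest other). The split that called 103 genes set kidney fresh 3, vitrified 2 and vitrified 4 against the rest. It was picked as the highest, only 4 of the 35 kidney splits called any gene, and what these libraries share was not tested.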
